A study of Penicillium oxalicum with 6 samples.

How the data were processed

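RNA was sequenced from mycelium of Penicillium oxalicum, a filamentous fungus that secretes cellulases and xylanases. Per the labels, the 6 libraries fall into 2 groups of 3, a strain mutated in POX05503 (MuPOX05503) and a strain mutated in Ku70. Ku70 takes part in non-homologous end joining, and fungal strains without it are commonly used for targeted gene replacement. The growth protocol names spores of the Ku70 mutant for all 6 libraries, and the labels do not say whether MuPOX05503 also carries the Ku70 mutation. This was not checked in the data, since no identifier is paired with Ku70. Per the labels' protocols, about 1 g of hyphae was moved to 100 mL of medium with Avicel, a microcrystalline cellulose, and shaken for 24 h (28 °C, 180 rpm); the titles give 1% Avicel. Total RNA was extracted with TRIzol and the libraries were sequenced on an Illumina HiSeq 4000 instrument. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

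The authors deposited 1 table per library with 9834 genes, each row holding a gene identifier, an expected count and an FPKM value. Per the file headers, the expected counts are estimated counts per gene, and their totals differ between libraries as those of values that are not normalized. The FPKM values, deposited beside them, are scaled to gene length and library depth. The gene length implied by the pair of values differed between libraries by a median factor of 1.00 among the 7650 genes with at least 100 counts. Per the submitters' processing notes, BWA 0.7.10-r789, Bowtie2 2.1.0, RSEM 1.2.12 and DESeq2 were used, with no role given for each. The genome build, the annotation and the strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. In each library 113 to 126 genes had an expected count that was not whole within 0.005, as arises when reads are shared between near-identical copies; 381 genes had such a count in at least 1 library, and 0 of these were members of the gene lists.

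Total expected counts ranged from 13653016 to 14263916 per library. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries was identical. Within a group, the chi-square statistic per degree of freedom between libraries was 10.5 to 47.3, so no pair differed as little as counting noise alone would give, as a library deposited again would; this does not show that the libraries came from separate cultures.

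The files do not pair the identifiers with gene names. Of the 9834 identifiers, 0 matched the RefSeq gene table of assembly ASM172317v3, and pairing by number alone gave gene lengths that did not correlate, so that table was not used. Before the data were examined, lists of 20 cellulase and 8 xylanase identifiers, recalled from publications on this strain, were fixed for this case. The list called cellulase was planned to take in beta-glucosidases, lytic polysaccharide monooxygenases and swollenins too. The list called xylanase was planned for xylanases and other hemicellulases. The membership could not be checked against the files. Those publications may include work on these libraries, in which case the lists are not independent evidence of a direction. The lists planned on gene products (among them starch and pectin degradation, sugar transport, known regulators, ribosome, central metabolism, secretion, stress, cell wall, conidiation and secondary metabolism) were not used, because they need names. Comparisons of enzyme classes within the cellulase list were also computed, with classes recalled after the data were examined, and are not reported here for that reason.

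Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the quasi-likelihood test and Benjamini-Hochberg adjustment. The design named a test on FPKM for files without counts and this count test for files with them. The 8801 genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, with strain as the only term. A gene passed at an adjusted p under 0.05, and a second count also required at least a 2-fold change. The lists were tested with camera (limma 3.58.1, preset correlation of 0.01, and an estimated one) and with fry. Fold changes are MuPOX05503 over Ku70. The rule for named genes took POX05503, the 10 highest and 10 lowest fold changes among genes that passed, did not overlap between strains and had a mean FPKM of at least 5 in the higher strain, the most significant and most abundant list members, and the 2 most abundant genes of each strain. Because identifiers without a name say little, 2 that rose and 2 that fell are printed outside the lists, besides POX05503, and the others are given without identifiers, as values or ranges.

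Alternatives were limma on log2(FPKM + 1) with other pseudocounts and scalings, DESeq2 1.42.0, other edgeR scalings and filters, a block on the letters F, S and T of the titles, and leaving out each library. The steps were tested on simulated counts of the 8801 genes for MuPOX05503 against Ku70. In them 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold, with as many raised as lowered. There edgeR recovered 64.2% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 98.5% of those changed 4-fold. Of its calls there, 4.49% were false. In the data 64.4% of tested genes passed, a far larger part, so these rates need not hold for them.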

Results

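The transcriptomes of P. oxalicum MuPOX05503 and Ku70 mycelium were compared after 24 h on 1% Avicel, with 3 libraries per strain. The comparison asks how deletion of POX05503 alters gene expression, in a series on protein kinases and the expression of cellulase and xylanase genes. Whether the strains differ in POX05503 alone is not stated in the labels, which do not say if MuPOX05503 also carries the Ku70 mutation. Total expected counts were 13653016 to 13843879 in the MuPOX05503 libraries and 13936580.3 to 14263916 in the Ku70 libraries. Between 9403 and 9451 genes had a count above 0 in a library. Log2(FPKM + 1) values correlated at 0.985 to 0.994 between libraries of one strain and at 0.841 to 0.857 between strains. The first principal component held 92.2% of the variance and separated the strains.

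The deleted gene had no reads in the mutant. POX05503 had an expected count of 0 in each of the 3 MuPOX05503 libraries. In the Ku70 libraries its count was 470 to 539, at a level of 24.3 ± 1.54 FPKM (SD, n = 3). With a floor of 3 counts over the 3 mutant libraries, POX05503 was at least 499.8-fold lower by library totals and at least 540.2-fold lower with TMM factors.

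Most cellulase and xylanase list genes were lower in the mutant, amid changes in a large part of the transcriptome. Of the 28 list genes, 26 fell, 1 rose and 1 did not pass the test. Together they took 3.69 ± 0.165% of all counts in Ku70 and 0.530 ± 0.0983% in MuPOX05503 (SD, n = 3). Of 8801 genes tested with edgeR, 5672 (64.4%) passed the threshold, 2804 of them higher and 2868 lower in MuPOX05503. At least 2-fold changes were found in 2234 genes, with 1010 higher and 1224 lower. Changes of at least 4-fold numbered 391 higher and 482 lower, and those of at least 16-fold numbered 91 and 90. The 3 libraries of one strain did not overlap with those of the other in 71.4% of the tested genes, where chance gives 10%. Scaling by library totals, without TMM factors, moved the median gene up by 0.11 on the log2 scale and turned the balance of directions, to 3341 higher and 2442 lower, or 1168 and 1088 with at least a 2-fold change. Fold changes are given on the TMM scale, and no list gene changed direction under any scaling tried.

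**Figure D1:**
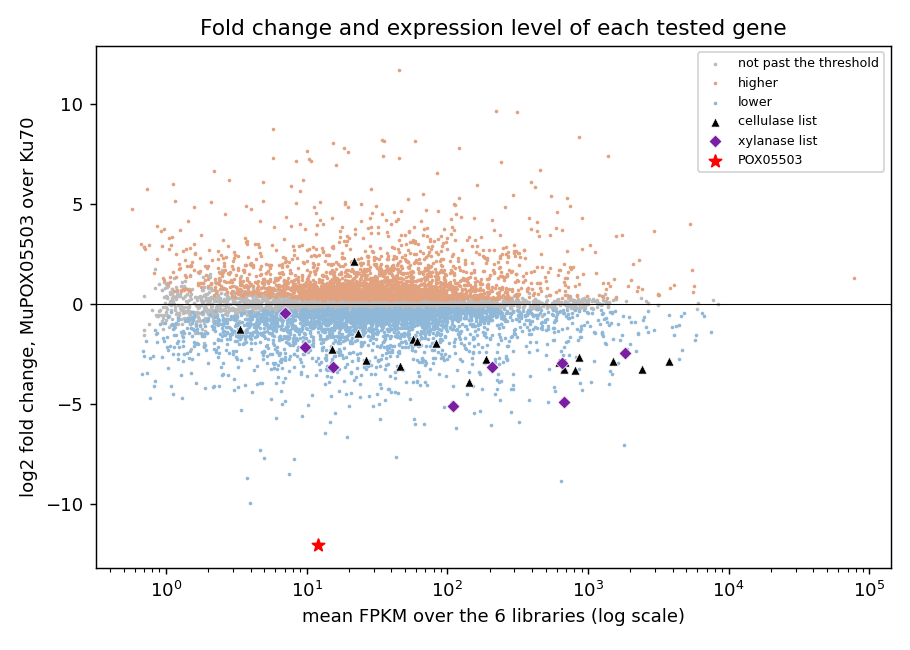
Log2 fold change of MuPOX05503 over Ku70 (vertical axis, edgeR) against mean FPKM over the 6 libraries (horizontal log axis), each point 1 of the 8801 tested genes, coloured as higher, lower or not past an adjusted p of 0.05. The list genes (triangles and diamonds) lie below 0 except POX07963, and the plotted value of a gene without reads in one strain, such as POX05503 (star), depends on the prior count of the fit.

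Cellulases hydrolyse cellulose, although a member of the cellulase list need not, given its wider scope. Of its 20 genes, 19 were lower in the mutant. All 20 members were tested, and 19 were lower and 1 higher, both over all genes and adjusted over the list alone. Membership rests on recalled publications that may include work on these libraries, so the list may not be independent evidence of its direction. The median log2 fold change was -2.84, equal to a 7.14-fold lower level. The share of all counts was 3.07 ± 0.162% in Ku70 and 0.442 ± 0.0839% in MuPOX05503 (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). The list was lower than other genes by camera with the preset correlation of 0.01 (adjusted p = 1.02e-15). The estimated correlation was far higher, 0.241, and with it camera gave an adjusted p of 0.0199. For a shift in one direction fry gave an adjusted p of 5.18e-06. That test asks whether the list genes changed at all, not whether they changed more than other genes, and 64.4% of all tested genes passed.

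The most abundant cellulase list gene, POX04786, fell from 6595 ± 598 to 978.5 ± 188 FPKM (SD, n = 3 here and below), with a log2 fold change of -2.87 (SE 0.17, edgeR adjusted p = 3.46e-07). Folds of list genes are those of edgeR on the TMM scale, and differ somewhat from the ratios of the FPKM values beside them. POX01166 fell 9.74-fold, from 4346 ± 193 to 482 ± 91.5 FPKM (adjusted p = 8.99e-08, edgeR). POX05587 fell 7.36-fold, from 2638 ± 693 to 389 ± 70.9 FPKM. POX02308 fell 10.1-fold, from 1470.3 ± 73.4 to 158 ± 21.9 FPKM. The largest fall within the list was that of POX08897, 15.3-fold, from 269 ± 20.5 to 19.0 ± 2.86 FPKM (adjusted p = 1.04e-08, edgeR). The smallest was that of POX08882, 2.41-fold, from 4.62 ± 0.588 to 2.06 ± 0.0929 FPKM. POX07963 rose 4.40-fold, from 7.50 ± 1.60 to 35.7 ± 2.26 FPKM (log2 fold change 2.14, SE 0.15, edgeR adjusted p = 1.26e-06).

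Xylanases cleave the xylan backbone of hemicellulose. The xylanase list was planned to include other hemicellulases too, and 7 of its 8 genes fell. The remaining gene, POX01237, did not pass over all genes; adjusted over the list alone, 8 were lower. The same limit on independence holds for this list. The median log2 fold change was -3.07, an 8.40-fold lower level. The share of all counts was 0.621 ± 0.0574% in Ku70 and 0.0876 ± 0.0144% in MuPOX05503 (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible). The list was lower than other genes by camera with the preset correlation of 0.01 (adjusted p = 7.05e-11). The correlation estimated from the data was far higher, 0.186, and with it camera gave an adjusted p of 0.0199. For a shift in one direction fry gave an adjusted p of 4.66e-06, again without a comparison with other genes.

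POX06601 fell 34.9-fold, from 215 ± 16.4 to 6.63 ± 2.97 FPKM (log2 fold change -5.13, SE 0.26, edgeR adjusted p = 1.45e-07). POX06783 fell 30.5-fold, from 1309.6 ± 106 to 46.3 ± 2.77 FPKM (log2 fold change -4.93, SE 0.12, edgeR adjusted p = 2.82e-09). POX08484, the most abundant of the xylanase list, fell 5.44-fold from 3069 ± 340 to 609 ± 90.4 FPKM. POX00063 fell 7.83-fold from 1141 ± 112 to 157 ± 36.2 FPKM. POX01237 was at 7.92 ± 0.957 FPKM in Ku70 and 6.16 ± 1.41 FPKM in MuPOX05503 (edgeR adjusted p = 0.0594). It passed without MuPOX05503 replicate 2 (adjusted p = 0.0176), without Ku70 replicate 3 (adjusted p = 0.0481) and with upper-quartile factors (adjusted p = 0.0397), and its adjusted p under all alternatives of edgeR, limma and DESeq2 ranged from 0.0176 to 0.171.

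**Figure D2:**
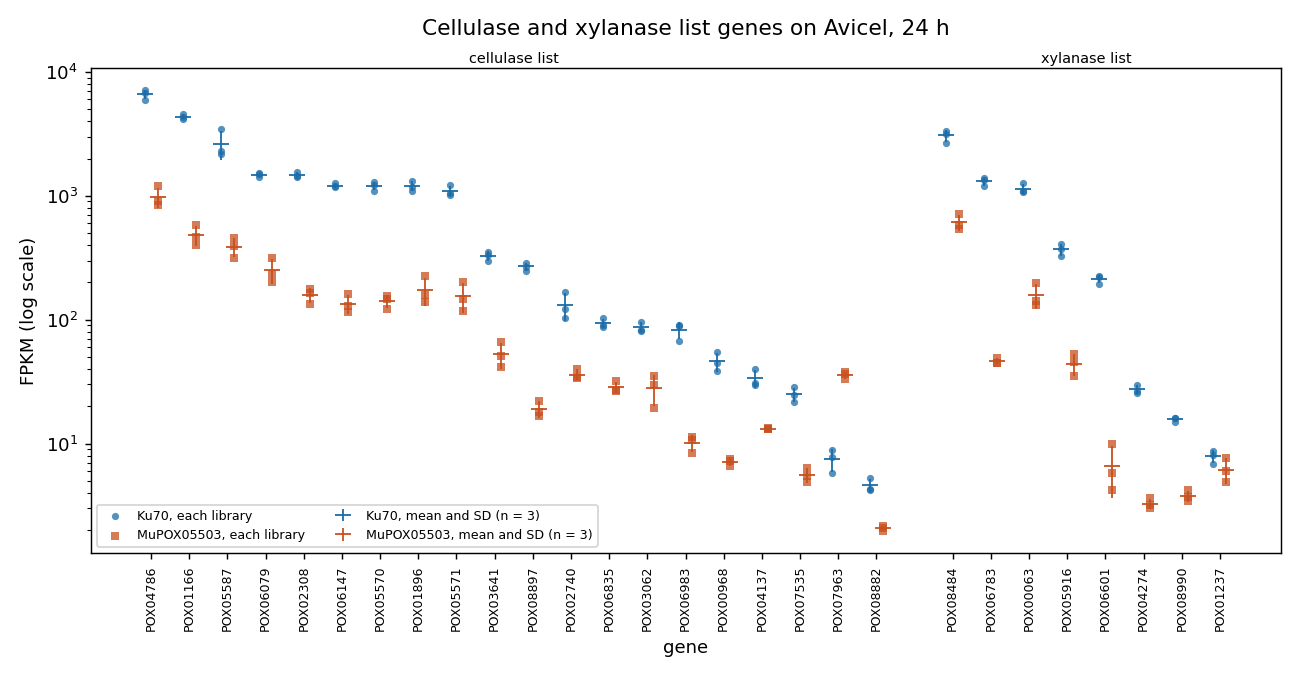
FPKM (vertical log axis) of the 28 cellulase and xylanase list genes in Ku70 (circles) and MuPOX05503 (squares), with each library as a point, means as horizontal ticks and SD as vertical bars (n = 3). The libraries of the strains do not overlap for any gene but POX01237, and MuPOX05503 is lower except at POX07963.

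The gene with the highest FPKM in all 6 libraries, POX01764, was higher in the mutant; the files do not name its product. It went from 42473 ± 2037 to 114067 ± 4821 FPKM (SD, n = 3; log2 fold change 1.31, SE 0.15, edgeR adjusted p = 3.59e-05). It took 2.01 ± 0.0948% of all counts in Ku70 and 5.40 ± 0.228% in MuPOX05503. Its expected counts were not whole, so its level is uncertain to the extent that reads were shared. The gene next in mean FPKM in Ku70 fell from 10673 ± 867 to 4368 ± 784 FPKM, and the one next in MuPOX05503 rose from 579 ± 97.8 to 10030 ± 1673 FPKM (SD, n = 3; edgeR adjusted p = 2.66e-05 and 5.22e-08).

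Some genes were nearly without reads in one strain. Among the 10 genes with the highest fold changes, mean FPKM ranged from 11.5 to 1735 in MuPOX05503 and was at most 4.90 in Ku70. POX08755 had expected counts of 381 to 461 in the mutant libraries and 0 in each Ku70 library, at least 409.99-fold higher with TMM factors and at least 443-fold higher by library totals, with a floor of 3 counts over the group. Apart from POX05503, the 9 genes with the lowest fold changes ranged from 7.51 to 3559 FPKM in Ku70 and reached at most 28.6 FPKM in MuPOX05503. POX07363 fell 463-fold, from expected counts of 11044 to 14244 in Ku70 to 14 to 44 in MuPOX05503 (adjusted p = 1.68e-08, edgeR). POX09831 had expected counts of 102.37 to 132.37 in Ku70 and at most 0.04 in MuPOX05503, at least 119-fold lower by library totals and at least 128.7-fold lower with TMM factors, with the same floor. Its counts were not whole, so its level is uncertain too.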

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

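Leaving out genes with counts that were not whole, and upper-quartile factors, were chosen after the data were examined. Under the alternatives run, no count of changed genes or list count moved by over 1.5 times, and no list test changed direction or its side of the threshold. The balance between higher and lower genes did depend on scaling: 49.4% of changed genes were higher with TMM, 57.8% with library totals, 57.6% with limma on log2(FPKM + 1) and 58.8% with totals without the 50 most abundant genes. At 2-fold, 1010 higher and 1224 lower became 1168 and 1088, 1030 and 977, and 1188 and 1074 under these. Leaving out each library gave 5029 to 5603 changed genes, and 2208 to 2255 with at least a 2-fold change. Each time 19 cellulase list genes and 7 to 8 xylanase list genes were lower. The limma test on log2(FPKM + 1) gave 5735 genes and DESeq2 5500, of which 5217 and 5452 were also among the 5672 with the same sign. Without genes of counts that were not whole 5480 passed, and with upper-quartile factors 5635. The replicate block on the title letters gave 5529 genes, 5447 of them shared with the unblocked test. Deviations from the group means correlated at 0.00, -0.03 and -0.02 between libraries of the same letter. Between strains the highest such correlation was 0.08, of MuPOX05503 replicate 2 with Ku70 replicate 3, which differ in letter. MuPOX05503 replicate 1 correlated best with Ku70 replicate 2 (0.06). A shared effect of a letter was thus not detected, and whether the letters mark a shared batch stays open. Of 697 values of list genes under these alternatives, 694 kept their side of the threshold, 0 reversed and 3 gained significance, all of POX01237. Quantile normalization set the fold change of POX01764 to 0 by construction, since the top rank gets the same value in every library. For genes at a count of 0 in one strain, depth allows only a lower bound on the fold: the fitted log2 fold change of POX08755 was 11.72 with edgeR and 6.52 with limma on log2(FPKM + 1).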

Other observations

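Tests of the count of changed genes, of the fall of the list genes and of their expression level were chosen after the results they measure were seen. Those on consecutive numbers were set out before their correlations were computed, although adjacent numbers had already been noticed among the most changed genes.

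Genes with consecutive identifier numbers changed together, and whether the numbers follow the chromosomes was not known. In 20 stretches, at least 5 consecutively numbered genes all passed the threshold with at least a 2-fold change in one direction, 15 stretches lower and 5 higher, with 118 genes in all. In 1000 random orders of the genes there were 0.383 stretches on average and 3 at most. The longest held 10 genes with log2 fold changes from -1.50 to -1.13, at a mean FPKM of 3169 in Ku70 and 1377 in MuPOX05503. Stretches of 9 and 8 genes fell with median log2 fold changes of -5.35 and -4.82. The longest stretch that rose held 7 genes, with a median log2 fold change of 2.66. The xylanase list gene POX06601 and the cellulase list gene POX07535 lay in stretches of 5 genes that fell. The genes numbered directly before and after POX05503, looked at because of the deletion, rose 1.48-fold and 1.99-fold (edgeR adjusted p = 0.00156 and 9.39e-06). The genes 2 numbers away on either side fell, with log2 fold changes of -0.71 and -0.72 (edgeR adjusted p = 0.0135 and 0.00417), those 3 numbers away did not pass, and 64.4% of all tested genes passed.

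Over all tested genes, log2 fold changes of consecutive numbers correlated at r = 0.245 across 8049 pairs, against at most 0.0337 in 1000 random orders; this is a correlation across genes, which are not independent replicates. Reads shared between near-identical copies are argued against, since r was 0.251 among genes with whole counts in every library. Overlap or read-through between adjacent transcripts was set out to give a correlation at a distance of 1 number only. At a distance of 2 r was 0.104, above all random orders (highest 0.03), which argues against this explanation as the whole of the pattern. At distances of 5, 10, 20 and 50 r was -0.002, 0.03, 0.00 and 0.02 (permutation p = 0.561, 0.012, 0.504 and 0.035, not adjusted), each below the highest of the random orders. As a part of the pattern, overlap or read-through stays open, a reading settled after the values were seen. Shared regulation of neighbouring genes, as in clusters of secondary metabolism, may also contribute and was not tested.

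Chance in how the libraries were grouped was examined with the other splits of the 6 libraries into 3 and 3. Of the 10 splits, 1, the real one, gave as many as 5672 changed genes, and likewise 1 gave as many as 2234 with at least a 2-fold change; the highest count of the other splits was 0 for both. With 10 splits, a share under 0.05 cannot be reached. Each other split also mixed the strains within both groups, so the strain difference added to the spread within groups. Low counts there were settled beforehand, and no conclusion on chance is drawn from them.

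The fall of 26 of the 28 list genes was set against technical explanations. The larger share of POX01764 in the mutant would lower all other genes by a log2 change of -0.05. The median of the 28 genes was -2.70 with that gene left out of the library totals, as so small a shift settles beforehand. That median is without TMM factors and does not compare directly with those on the TMM scale. The size of the shift argues against dilution by that gene. Genes abundant in Ku70 tended to be lower: of the 100 most abundant there, 74 fell and 11 rose (median log2 fold change -1.01). Of the 100 most abundant in MuPOX05503, 30 fell and 42 rose (median log2 fold change 0.19). Choosing genes by their level in one strain favours such a trend, but the sets did not mirror each other. Random lists matched on mean FPKM over both strains typically had a median of 0.005, and those matched on FPKM in Ku70 one of -0.22. The size of these medians argues against such a trend as the whole of the fall. Of 10000 random lists of either kind, 0 had a median as low as -2.87 (lowest -0.85 and -1.46). Their members were drawn independently, while list genes were correlated (estimated at 0.241 and 0.186), so that count may overstate how rare such a median is. The lists may also rest on work on these libraries. A difference between the strains in growth or in progress on cellulose at 24 h stays open as untested, as does an effect of the deletion on these genes.

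Among the 28 list genes, those with a higher mean FPKM may have fallen more (Spearman rho = -0.52, permutation p = 0.00573; Pearson r = -0.49, permutation p = 0.00565; r = -0.47 without the 2 genes farthest from the median level). This is 1 relation across genes that are not independent replicates. The mean FPKM and the fold change both rest on the level in Ku70, so the relation may come in part from that. A difference between the xylanase and cellulase lists was not detected (difference in mean log2 fold change -0.64, exact two-sided permutation p = 0.253, 8 and 20 genes).

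Expected counts rounded to 0 in all mutant libraries for 4 genes with at least 30 counts over the Ku70 libraries, POX05503 among them, and 3 genes showed the opposite.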
